A study of Homo sapiens with 58 samples.

How the data were processed

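RNA was measured in whole blood of 29 people who took part in training with exposure to moderate blast. Each gave a tube at baseline and another on day 10, the last day of training, so that 58 libraries were analysed here, 29 per time point. The tubes hold a reagent that lyses the cells and stabilises RNA when blood is drawn, and they stood at room temperature before freezing, per the labels' protocols. No library of people without blast exposure was used here, and the change from baseline to day 10 therefore covers everything that differed between the 2 draws. The series' design text speaks of microRNA profiling in 24 samples, which does not describe these gene count files. The time point of each library was taken from its label and the participant from its title. The baseline title of 1 participant carries another end number than all other baseline titles.

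The deposited values are raw read counts per gene, as whole numbers, and the authors had not normalised them. Read quality was assessed with FastQC 0.11.5, reads were aligned with STAR to the human genome build hg19, and genes were counted with HTSeq 0.6.1p1, per the submitters' processing notes, which also name DESeq2 1.12.3. The STAR version, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not be separable. HTSeq sets aside a read that aligns to more than 1 place, which affects genes with near-identical copies such as the globin genes HBA1 and HBA2 and the ribosomal protein genes with their pseudogenes. The count files list 26364 gene symbols and 5 classes that name no gene. These classes were left out of library totals and tests. Reads in no annotated feature made up 11.5% ± 2.12 (SD, n = 29) of reads aligned to a unique place at baseline and 10.5% ± 2.25 at day 10, ambiguous reads 1.64% ± 0.201 and 1.53% ± 0.154, and alignments that were not unique 53.4% ± 7.08 and 57.2% ± 8.37 of all entries. The share of mitochondrial genes, a planned measure, was not analysed here.

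XIST and the genes on the Y chromosome, 108 symbols with 0.0368% of the counts, were left out of all tests. Totals of gene counts ran from 25781820 to 49584879 per library. HBB took 24.2% of all gene counts and HBA1 with HBA2 took 7.92%, which lowers the depth left for other genes.

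Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 13792, and libraries were scaled with TMM. Dispersions and the robust quasi-likelihood fit had the participant as a block, and the quasi-likelihood F test compared day 10 with baseline, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are given with their standard error (SE), and levels as CPM, counts scaled to a common library size with the TMM factors. The gene CPM, carboxypeptidase M, is named as such. A gene is said to rise, fall or change only if it passed this test. The pairing comes from the titles, which name the participant. Deviations from the time point means correlated above 0.1 in 26 of 29 pairs, with a median of 0.577 and a lowest value of -0.172, against a median of -0.018 between different participants. In a check for mixed-up samples on the 100 genes that varied most between participants at baseline, the libraries of 27 participants matched each other best. The 4 libraries of the other 2 participants did not match their own titles and matched crosswise. The baseline library of each of these 2 and the day 10 library of the other matched best, reciprocally. A fit with their pairing exchanged was not made. All 58 libraries were kept in the pairing the titles give, so counts of participants by direction include these 2, and the fit without these 2 participants is among the alternatives.

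Gene lists, 31 in all, were written before the data were examined: markers of blood cell types, responses to stress, injury and handling, and genes around the amyloid precursor protein. Lists were tested with camera (limma 3.58.1) on voom log2 values with the participant block and a preset correlation between genes of 0.01, with adjustment over the 31 lists. Each was also tested with a correlation estimated from the data and with fry, whose directional p asks whether the list's genes move on balance to one side. Members were counted from the gene test, adjusted over all genes and adjusted over the list alone. Library measures were compared with a two-sided sign-flip permutation test of the paired differences with 100000 resamples, adjusted over the measures. The sample titles also hold a letter that the labels do not explain. Whether the change differed between letters was tested in the 28 participants of the 6 letters with 4 to 5 participants each, as the letter by time point terms of the same edgeR model.

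The genes named were chosen by a rule set before the data were examined. Among genes past the threshold with an average log2 level of at least 2 and the same direction in at least 20 of 29 participants, the rule took the 10 with the highest and the 10 with the lowest log2 fold change and the 5 with the lowest p in each direction. It added APP and, from each list, the 3 measured members with the lowest p. Other members of a list are named as examples that were chosen after their values were seen.

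The steps were tested on simulated data. Counts were drawn for the 13792 genes with the real means and library sizes, the same dispersion for every gene and no correlation between genes. Of 100 genes changed by 1.2-fold between baseline and day 10, 44 were recovered, and of 100 genes changed by 1.5-fold all 100, with 6 unchanged genes among 150 calls. Of 200 genes changed by 2-fold in participants of 1 letter, 129 were recovered with 7 other calls. Real genes differ in dispersion and move together, so these numbers may not hold for the real data.

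Alternatives set before the data were examined were other scalings (median of ratios and upper quartile), no low-count filter or a minimum count of 50, DESeq2 1.42.0, limma-voom with a fixed or random participant effect, no participant block, globin genes left out, marker scores of erythroid cells, neutrophils and T cells as covariates, the share of reads in no feature as a covariate, a test against a fold of 1.2, and fits without the participant with the differing title, without each title letter and without each participant. Alternatives added after the data were seen were the fit without the 2 participants whose libraries did not match, an offset that removes each library's trend on GC content and transcript length, and covariates for T and B cell, monocyte, platelet and immediate early gene scores and for alignments that were not unique. A score is the mean log2 level of a list's measured members. GC content and length came from a reference on another genome build, matched by symbol for 97.3% of the tested genes, and no coordinates were taken from it. Each gene was given the values of its longest listed transcript.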

Results

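Gene expression was compared between baseline and day 10 of training in whole blood of 29 people exposed to moderate blast. Whole blood RNA comes from neutrophils, lymphocytes, monocytes, platelets and young red cells together. Gene counts totalled 38958754 ± 5122671 per library at baseline and 36580901 ± 4427399 at day 10 (SD, n = 29 each; adjusted p = 0.0406, permutation test). Globin genes, the product of red cell precursors, took 31.5% ± 11.6 of counts at baseline and 34.1% ± 11.9 at day 10 (adjusted p = 0.23), with a range from 11.3% to 57.9% over the libraries. Other library measures moved with the time point. Day 10 libraries had fewer detected genes, 16998 ± 454 against 17274 ± 452 (adjusted p = 0.0125), a smaller share of reads in no feature (adjusted p = 0.0125) and a larger share of alignments that were not unique (adjusted p = 0.0162).

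The comparison of day 10 with baseline asks how blood gene expression changed over training with blast exposure. Genes of monocytes and genes that respond to glucocorticoids rose, and genes of B cells, T cells and the cytosolic ribosome fell. With an estimated correlation between genes, only the glucocorticoid-responsive list was still called (adjusted p = 0.0349), against 0.116 and 0.235 for the monocyte lists, 0.158 for B and T cells and 0.289 for the ribosome. VCAN, the monocyte proteoglycan versican, was 1.55-fold its baseline level at day 10, at 232 ± 82.8 CPM against 149 ± 49.6 (SD, n = 29; log2 change 0.64, SE 0.070, adjusted p = 4.5e-07), and was higher in 29 of 29 participants. TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein, was 1.36-fold its baseline level and higher in 28 of 29 (SE 0.054, adjusted p = 2.1e-06). TCL1A, a gene of naive B cells, was at 0.733 of its baseline level and lower in 28 of 29 (log2 change -0.45, SE 0.054, adjusted p = 1.7e-06). APP, the gene of the amyloid precursor protein, was 1.26-fold its baseline level and higher in 21 of 29 (log2 change 0.33, SE 0.084, adjusted p = 0.00471).

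The changes were many and small. In edgeR's quasi-likelihood test 4477 of 13792 genes changed (32.5%), 2322 higher and 2155 lower, with a median absolute log2 change of 0.26. A change over 1.5-fold was found for 65 genes that rose and 136 that fell. Under the naming rule, which needs an average log2 level of at least 2 and the same direction in at least 20 of 29 participants, the genes with the highest fold changes were CRISPLD2, which encodes a secreted protein that binds lipopolysaccharide (log2 change 0.79), PI3, the elastase inhibitor elafin (0.76), RPH3A (0.72), the insulin receptor adaptor GRB10 (0.69), SPOCD1 (0.68), the calmodulin-dependent kinase kinase CAMKK1 (0.67), the mitochondrial aldehyde dehydrogenase ALDH2 (0.66), TBC1D8 (0.65) and the carboxylesterase CES1 (0.64), beside VCAN. Their adjusted p values ran from 4.5e-07 for VCAN to 0.00277 for SPOCD1. Lowest under this rule were the ribosomal protein genes RPL34 (log2 change -0.74), RPL39 (-0.68), RPL9 (-0.64), RPL26 (-0.64) and RPL31 (-0.63), with COMMD6 (-0.70), the potassium channel gene KCNG1 (-0.67), the long noncoding RNA LINC00926 (-0.64), PDK4, a kinase that inhibits pyruvate dehydrogenase (-0.62), and ZNF302 (-0.59). RPL34 varied widely, with an SE of 0.23 and an adjusted p of 0.0186. At baseline the SD exceeded the mean for RPL34, RPL39, RPL9, RPL26, RPL31 and COMMD6. RPL34 stood at 41.9 ± 78.5 CPM at baseline and 15.9 ± 9.33 at day 10. The genes with the lowest p under the same rule included, besides VCAN and LINC00926, DAPK1, the death-associated protein kinase (log2 change 0.43, higher in 29 of 29), the Golgi mannosidase MAN2A2 (0.33), the fatty acyl reductase FAR2 (0.47) and carboxypeptidase M, whose gene symbol is CPM (0.53), rose, and HAPLN3, a hyaluronan link protein (-0.43), FAM129C (-0.47) and the somatostatin receptor SSTR3 (-0.43) fell.

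The number of genes depended on the model. It was 1379 (552 higher, 827 lower) with no replicate block, 189 with erythroid, neutrophil and T cell scores as covariates, 97 with T and B cell scores, 174 with the monocyte score, 2320 without the participants of title letter C and 2818 without those of letter D, and upper quartile scaling split it into 1510 higher and 3245 lower, against 2322 and 2155 with TMM.

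**Figure D1:**
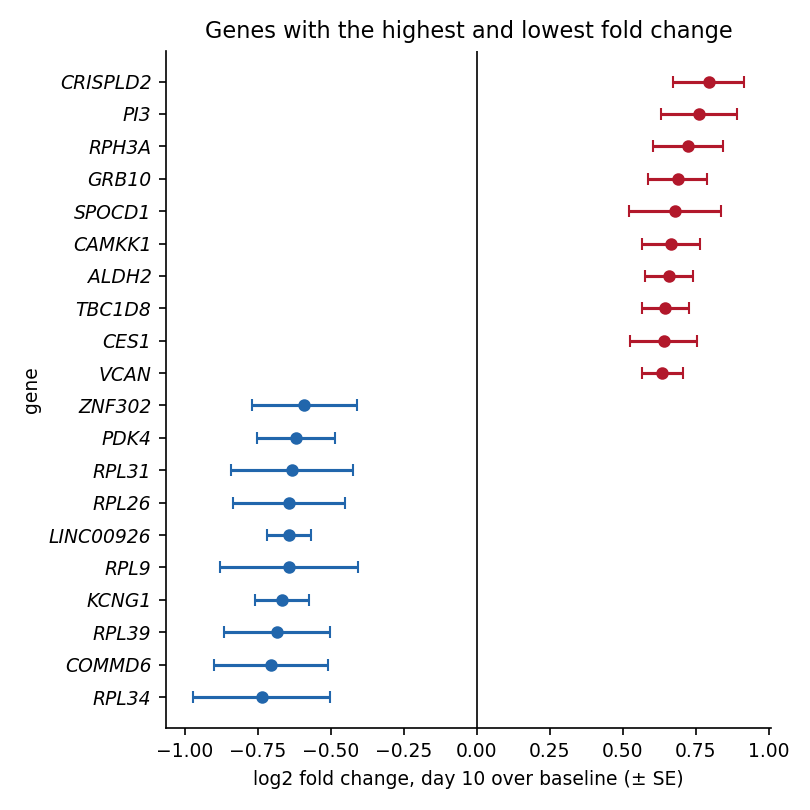
Log2 fold change of day 10 over baseline (x axis) for the 10 genes with the highest and the 10 with the lowest fold change under the naming rule, with bars of 1 SE (n = 29 participants). CRISPLD2 (0.79) and RPL34 (-0.74) are at the ends, and the ribosomal protein genes have wider bars than most genes that rose.

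APP is a membrane protein from which amyloid beta is cut, and in blood its gene is used most by platelets and leukocytes. APP averaged 47.6 ± 14.3 CPM at baseline and 58.4 ± 11.2 at day 10 (SD, n = 29), a log2 change of 0.33 with a 95% interval from 0.16 to 0.51 (edgeR p = 0.000369). The 8 participants in whom APP was lower at day 10 all had baseline levels of 52.35 CPM or more. All participants who started below that level were higher at day 10, and those at or above it went both ways. Whether the change depends on the baseline level was not tested. Of the 59 measured genes of the list for processing or binding of the protein, 24 rose and 4 fell, and 25 rose and 4 fell adjusted over the list alone. Besides DAPK1, LRP1, the receptor that takes up APP and lipoproteins (0.54), and APLP2, a homologue of APP (0.39), rose, as did the gamma-secretase gene NCSTN (0.32). NCOA4 (0.27), which the list also holds, rose too, and its tie to the protein was not tested here. The list was called up (camera adjusted p = 2.7e-05; adjusted p = 0.236 with an estimated correlation). Its median went from 0.14 to 0.043 with the erythroid, neutrophil and T cell scores as covariates, 0.013 with the T and B cell scores and -0.028 with the monocyte score, and the call was lost with each (camera adjusted p = 0.389, 0.79 and 0.556). In the same libraries the classical monocyte markers had a median log2 change of 0.30 and the platelet genes of 0.24. APP no longer passed with the monocyte score as a covariate (log2 change -0.00097, SE 0.10, adjusted p = 0.997), with the erythroid, neutrophil and T cell scores (0.059, adjusted p = 0.807), with the T and B cell scores (0.16, adjusted p = 0.69) or with the platelet score (0.24, adjusted p = 0.0761). It also missed the threshold with the immediate early score (0.21, adjusted p = 0.242), the share of reads in no feature (0.31, adjusted p = 0.0519) or that of alignments that were not unique (0.24, adjusted p = 0.0773) as a covariate, and in a test against a fold of 1.2 (adjusted p = 0.756).

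**Figure D2:**
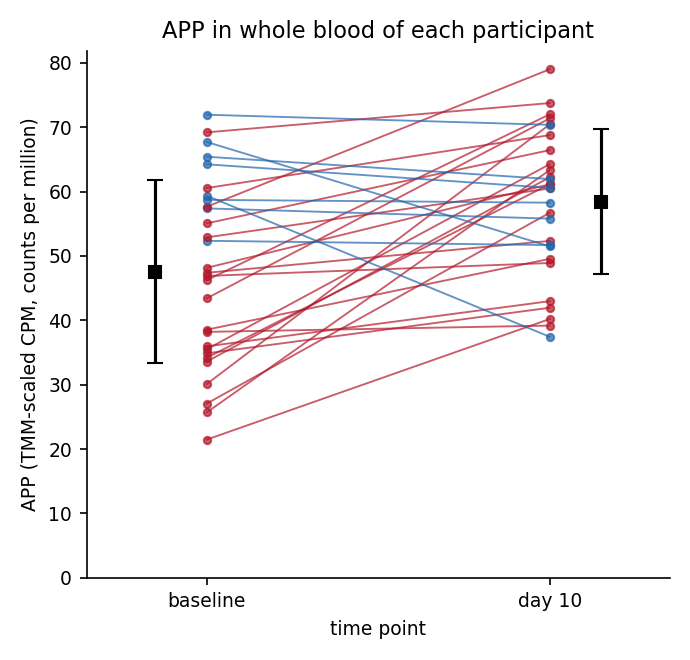
APP in TMM-scaled CPM (y axis) at baseline and day 10 (x axis), with 1 line per participant, red where APP was higher at day 10 (21 of 29) and blue where it was lower. Black squares with bars are the mean and SD of 29 libraries, 47.6 ± 14.3 and 58.4 ± 11.2.

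Monocyte genes rose. Of 20 classical monocyte markers 15 rose and 0 fell, and 18 rose and 1 fell adjusted over the list alone. Besides VCAN these included PLBD1 (log2 change 0.62), the lipid antigen presenting molecule CD1D (0.51) and CD14, the lipopolysaccharide co-receptor (0.47). The median change was 0.30, with a higher median in 26 of 29 participants (camera adjusted p = 8.4e-10; adjusted p = 0.116 with an estimated correlation). The classical median was 0.18 with 4 members higher with the erythroid, neutrophil and T cell scores as covariates. With the T and B cell scores it was 0.14 with 3 higher, and camera called the list with either (adjusted p = 1e-05 and 1.1e-05). Of 16 non-classical monocyte markers 11 rose and 0 fell, also adjusted over the list alone, with a median of 0.35. Among them were the inhibitory receptor SIGLEC10 (0.53), LILRA1 (0.47) and the transcription factor TCF7L2 (0.36), and the complement gene C1QB rose by 0.94 (camera adjusted p = 1.4e-05; adjusted p = 0.235 with an estimated correlation). The non-classical median was 0.034, 0.048 and 0.075 with the erythroid, neutrophil and T cell, the T and B cell and the monocyte scores as covariates, and the call was lost with each (camera adjusted p = 0.796, 0.133 and 0.153). Platelet and megakaryocyte genes had 16 of 36 members higher and 0 lower (17 and 0 adjusted over the list alone), with coagulation factor F13A1, which monocytes also express (0.54), the fibrinogen receptor chain ITGB3 (0.42) and the cyclooxygenase PTGS1 (0.38). Their median was 0.24 (camera adjusted p = 4.6e-06; adjusted p = 0.303 with an estimated correlation). Without letter A 5 rose, without letter C 6, and with the erythroid, neutrophil and T cell scores 0 (median 0.046, camera adjusted p = 0.148). The coagulation and vascular injury list, 8 of whose members are in other lists, had 14 of 32 higher and ICAM2 lower, with the same counts adjusted over the list alone. The matrix inhibitor TIMP2 (0.45), the adhesion molecule ICAM1 (0.44) and von Willebrand factor, VWF (0.50), rose (camera adjusted p = 5e-05; adjusted p = 0.158 with an estimated correlation). This call was lost with each of the 3 sets of cell scores (camera adjusted p = 0.453, 0.709 and 0.495).

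Lymphocyte genes fell. Of 26 B cell markers 23 fell and 0 rose, and 24 fell adjusted over the list alone. The median log2 change was -0.34, and the median was higher in 3 of 29 participants (camera adjusted p = 1.5e-13; adjusted p = 0.158 with an estimated correlation). Besides TCL1A, the B cell transcription factor PAX5 (-0.41) and the IgE receptor FCER2 (-0.39) fell. The B cell median was -0.16 with 3 members lower with the erythroid, neutrophil and T cell scores as covariates. With the monocyte score it was -0.13 with 2 lower, and camera called the list down with either (adjusted p = 7.7e-08 and 0.00219). Of 34 T cell markers 27 fell, and 28 adjusted over the list alone, among them NELL2 (-0.45), MAL (-0.36), TRABD2A (-0.37) and the T cell receptor chain CD3D (-0.33). CD4, which monocytes also express, was the member that rose (0.21). The T cell list had a median of -0.22 (camera adjusted p = 8.4e-10; adjusted p = 0.158 with an estimated correlation), which was -0.013 with the monocyte score as a covariate (camera adjusted p = 0.998). Cytotoxic lymphocyte genes went both ways, with 5 of 36 higher and 3 lower (3 and 1 adjusted over the list alone). CD244 (0.19) and SPON2 (0.45) rose, the granzyme gene GZMK fell (-0.47), and the list was not called (camera adjusted p = 0.367).

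Ribosomal protein genes fell together with the lymphocyte genes. Of 74 cytosolic ribosomal protein genes 65 fell and 0 rose, and 67 fell adjusted over the list alone. RPL13A (log2 change -0.36), RPL32 (-0.32) and RPL22 (-0.29) had the lowest p. The median was -0.31, and the list had a higher median in 8 of 29 participants (camera adjusted p = 1.3e-17; adjusted p = 0.289 with an estimated correlation, which was 0.668 between its genes). Its median was -0.024 with the T and B cell scores, -0.0040 with the monocyte score and 0.0039 with the erythroid, neutrophil and T cell scores as covariates. Of 76 nuclear genes of oxidative phosphorylation 19 fell and 5 rose (18 and 5 adjusted over the list alone). NDUFV2 (-0.16) and NDUFS5 (-0.28), subunits of complex I, fell and UQCRC1, a subunit of complex III, rose (0.27). This list's median was -0.040 (camera adjusted p = 0.0275; adjusted p = 0.669 with an estimated correlation). That call was lost with the GC and length offset (camera adjusted p = 0.316), without letter A (0.058), with no replicate block (0.0644) and with each set of cell scores, and 2 fell without letter C.

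Of 26 neutrophil markers 8 rose and 0 fell, also adjusted over the list alone, such as the chemokine receptor CXCR2 (log2 change 0.36), the formyl peptide receptor FPR2 (0.34) and histidine ammonia lyase, HAL (0.30), with camera adjusted p = 0.00265 and adjusted p = 0.561 with an estimated correlation. Without letter C 0 of them rose and the call was lost (camera adjusted p = 0.0518), and the median turned from 0.19 to -0.17 with the T and B cell scores and to -0.22 with the monocyte score as covariates. Granule genes of immature neutrophils had 9 of 22 higher and 0 lower (11 and 0 adjusted over the list alone), with ARG1 (0.67), MPO, myeloperoxidase (0.47), and BPI (0.44), and the highest median of the 31 lists, 0.42 (camera adjusted p = 0.000377; adjusted p = 0.415 with an estimated correlation). Only 1 of them rose without letter A (median 0.28), C or D, and the call was lost without letter D (camera adjusted p = 0.113) and with the share of reads in no feature as a covariate (0.161). Of 49 erythroid genes 10 rose and 0 fell, and 6 rose adjusted over the list alone. They included RNF10 (0.38), the mitochondrial iron importer SLC25A37 (0.32) and HBA1 (0.57), whose reads cannot be fully separated from those of HBA2 (camera adjusted p = 8.8e-06; adjusted p = 0.5 with an estimated correlation). This list moved with the participants and the model: 23 rose without the participant with the differing title and 2 without letter A, and the share of reads in no feature as a covariate turned its median from 0.26 to -0.089 with 0 members past the threshold (camera adjusted p = 0.0168; adjusted p = 0.713 with an estimated correlation). Eosinophil markers had 7 of 19 higher and 0 lower, also adjusted over the list alone, with the eotaxin receptor CCR3 (0.32), SLC29A1 (0.36) and PTGDR2 (0.30) (camera adjusted p = 0.00147; adjusted p = 0.303 with an estimated correlation), a call lost with the erythroid, neutrophil and T cell scores (camera adjusted p = 0.204) and the monocyte score (0.998, median -0.065). Of 10 basophil markers 4 rose and 1 fell (5 and 1 adjusted over the list alone). AKAP12 rose (0.64), FCER1A, the IgE receptor chain also found on dendritic cells, fell (-0.51), and the list was not called (camera adjusted p = 0.0699). Of 17 dendritic cell markers 4 fell, TCF4 (-0.28), CD1E (-0.44), CD1C and FCER1A, and FLT3 rose (0.44), with the same counts adjusted over the list alone (camera adjusted p = 0.545). Of 14 plasma cell markers POU2AF1 fell (-0.25) and SDF2L1 rose (0.14). TNFRSF17 had a log2 change of -0.60 (adjusted p = 0.0682), and adjusted over the list alone 1 fell and 0 rose (camera adjusted p = 0.545).

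**Figure D3:**
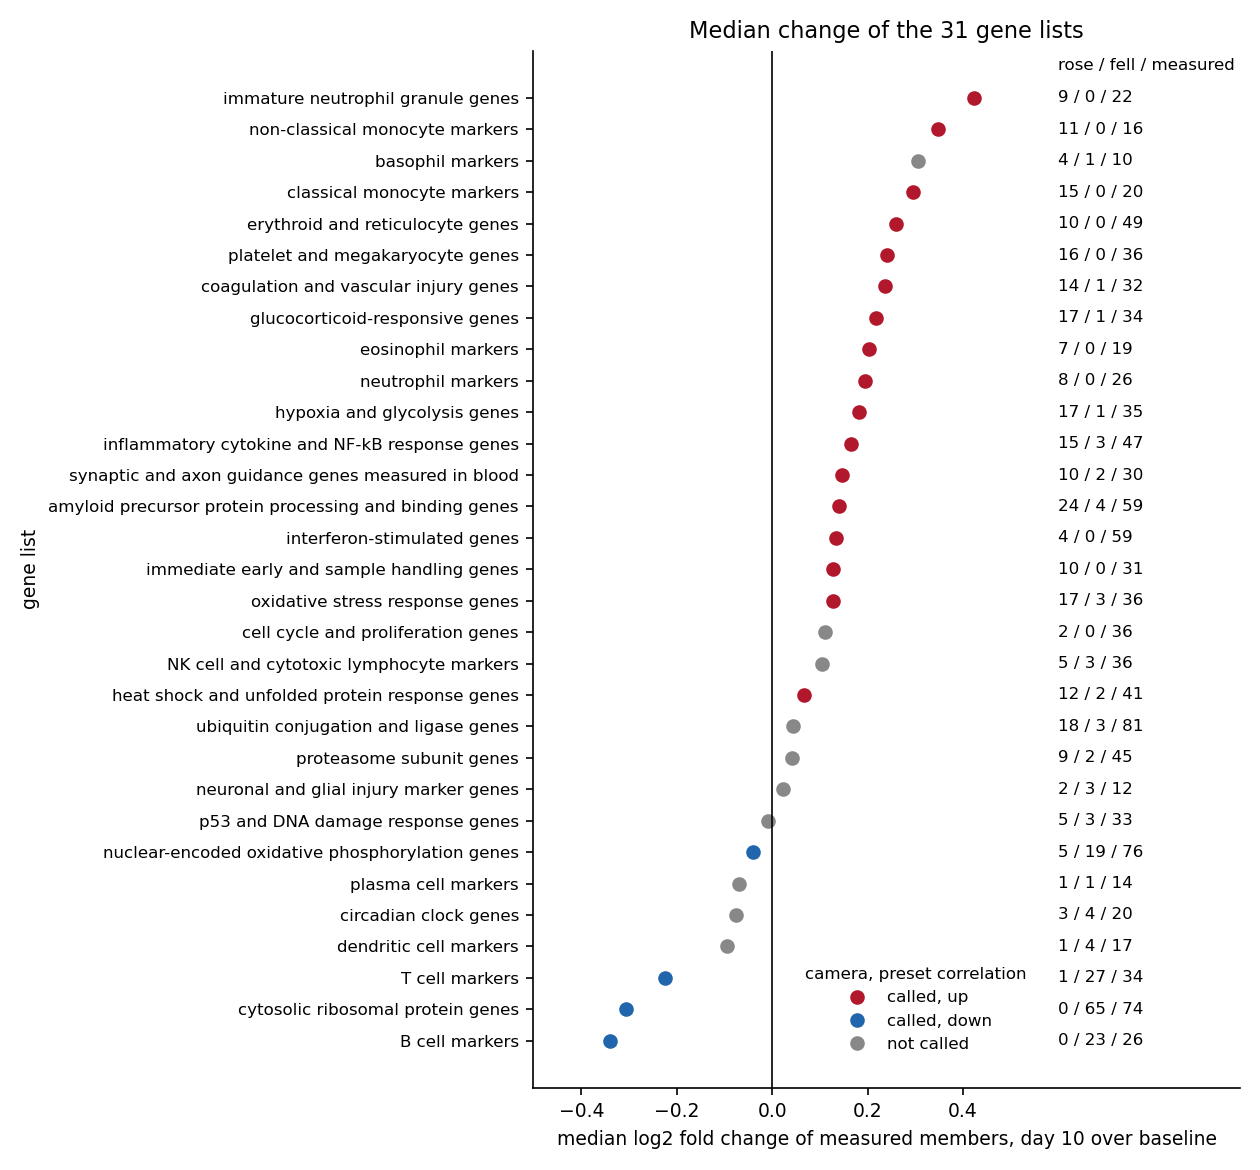
Median log2 fold change of day 10 over baseline (x axis) of the measured members of each of 31 gene lists (y axis), with the numbers that rose, fell and were measured at the right. Point colour gives the camera call with a preset correlation of 0.01. B cell markers (-0.34) have the lowest median and immature neutrophil granule genes (0.42) the highest, and upper quartile scaling turns the medians of the neuronal injury, proteasome and ubiquitin lists below 0.

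Glucocorticoid-responsive genes rose in most participants. Of 34 such genes 17 rose and 1 fell (19 and 1 adjusted over the list alone). TSC22D3 (log2 change 0.45), the phagocytic receptor MERTK (0.93), the stress-induced inhibitor of mTOR DDIT4 (0.49) and FKBP5, a chaperone of the glucocorticoid receptor (0.53), rose, and TSPYL2 fell (-0.20). The median was 0.22, the participants' own median was higher at day 10 in 26 of 29, and 15 of the members are in other lists. Camera called the list with the preset correlation (adjusted p = 1.2e-07), and it was the 1 list of 31 still called with an estimated correlation (adjusted p = 0.0349). That call was lost with a minimum count of 50 (adjusted p = 0.0644), with the GC and length offset (0.0774), with the monocyte score (0.416) and without letter B (0.12), C (0.11), D (0.0568), E (0.0626) or F (0.115). Under upper quartile scaling the classical monocyte and coagulation lists were called with an estimated correlation as well (camera adjusted p = 0.0376 for each). Immediate early genes, which also respond to blood handling, had 10 of 31 higher and 0 lower, also adjusted over the list alone. They included KLF4 (0.39) and the MAP kinase phosphatases DUSP6 (0.28) and DUSP1 (0.34) (camera adjusted p = 0.00132; adjusted p = 0.289 with an estimated correlation). The immediate early call was lost with each set of cell scores (camera adjusted p = 0.534, 0.754 and 0.951).

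Of 35 hypoxia and glycolysis genes 17 rose and 1 fell (18 and 1 adjusted over the list alone). Among them were the oxygen-regulated transcription factors EPAS1 (log2 change 0.57) and HIF1A (0.32), and the hexokinase HK1 (0.39) (camera adjusted p = 1.7e-05; adjusted p = 0.2 with an estimated correlation). The list's median went from 0.18 to 0.040 with the erythroid, neutrophil and T cell scores as covariates, 0.0066 with the T and B cell scores and -0.022 with the monocyte score, and camera no longer called it (adjusted p = 0.207, 0.79 and 0.998). Oxidative stress response genes had 17 of 36 higher and 3 lower (19 and 3 adjusted over the list alone). Glutathione reductase, GSR (0.24), thioredoxin reductase, TXNRD1 (0.30), and heme oxygenase, HMOX1 (0.39), rose (camera adjusted p = 0.00104; adjusted p = 0.289 with an estimated correlation). With the same 3 sets of cell scores this median went from 0.13 to 0.017, 0.038 and -0.0024, and the call was lost (camera adjusted p = 0.406, 0.404 and 0.998). Heat shock and unfolded protein response genes had 12 of 41 higher and 2 lower, also adjusted over the list alone. The chaperones CANX (0.17) and DNAJB6 (0.22) rose and HSPE1 fell (-0.37), with a list median of 0.068 (camera adjusted p = 0.0294; adjusted p = 0.304 with an estimated correlation). The call was lost with upper quartile scaling (camera adjusted p = 0.0558, median 0.017, 7 higher and 5 lower), with no low-count filter (0.117), with a minimum count of 50 (0.0999) and with each set of cell scores. Of 47 inflammatory genes 15 rose and 3 fell (16 and 3 adjusted over the list alone). The inflammasome sensor NLRC4 (0.47) and IRAK3, an inhibitor of Toll-like receptor signalling (0.47), rose, and CD83, a marker of activated dendritic cells and lymphocytes, fell (-0.39) (camera adjusted p = 0.000531; adjusted p = 0.289 with an estimated correlation). This list's median turned from 0.17 to -0.068 with the T and B cell scores and to -0.093 with the monocyte score, with 0 members higher under either. Interferon-stimulated genes had 4 of 59 higher and 0 lower, and 0 adjusted over the list alone. MX2 (0.27), PARP14 (0.25) and STAT2 (0.21) had the lowest p (camera adjusted p = 0.00147; adjusted p = 0.561 with an estimated correlation). The direction of this list is not established: the 3 sets of cell scores turned its median from 0.13 to -0.15, -0.15 and -0.18, and 12 members rose without letter A but 0 without letter C.

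Neuronal and glial injury markers gave no common direction in blood. Of 25 such genes 12 were measured, of which 2 rose and 3 fell (3 and 3 adjusted over the list alone). Neuron-specific enolase, ENO2 (log2 change -0.22), and the neurofilament gene NEFM (-0.73), which lay at 0.408 CPM at baseline, fell. NRGN, neurogranin, rose (0.42) and is also in the platelet list. The list's median was 0.022, its mean -0.019, and its camera adjusted p 0.952. Synaptic and axon guidance genes had 10 of 30 higher and 2 lower (12 and 4 adjusted over the list alone). The semaphorins SEMA6B (1.23) and SEMA7A (0.40) rose and the ephrin receptor EPHA4 fell (-0.52) (camera adjusted p = 0.0294, and 0.303 with an estimated correlation). SEMA6B lay at a low level, 0.94 ± 1.1 CPM at baseline (SD, n = 29). The call was lost with no low-count filter (camera adjusted p = 0.238), a minimum count of 50 (0.109) and the GC and length offset (0.0887), and the median turned from 0.15 to -0.044 with the erythroid, neutrophil and T cell scores and to -0.12 with the monocyte score. Circadian clock genes had 3 of 20 higher and 4 lower (4 and 5 adjusted over the list alone), with NPAS2 lower (-0.49) and BHLHE40 (0.26) and PER2 (0.20) higher (camera adjusted p = 0.66).

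Of 45 proteasome genes 9 rose and 2 fell (7 and 2 adjusted over the list alone). PSME3 (log2 change 0.22), PSMD2 (0.23) and PSMF1 (0.27) had the lowest p, and the list was not called (camera adjusted p = 0.195). Of 81 ubiquitin conjugation and ligase genes 18 rose and 3 fell (11 and 3 adjusted over the list alone). The ligase genes CBL (0.28) and RNF123 (0.27) rose, and RPS27A, which encodes ubiquitin fused to a ribosomal protein, fell (-0.36) (camera adjusted p = 0.0699). With upper quartile scaling the medians of the proteasome list (0.042), the ubiquitin list (0.044) and the neuronal injury list (0.022) became -0.0079, -0.0067 and -0.024. Cell cycle genes had UBE2C (0.46) and AURKA (0.29) higher of 36, 0 lower and 0 adjusted over the list alone, and KIF20A had a log2 change of 0.30 (adjusted p = 0.0671; camera adjusted p = 0.234). Of 33 p53 and DNA damage genes 5 rose and 3 fell, also adjusted over the list alone. GADD45A (0.34) and SESN2 (0.30) rose and AEN fell (-0.17), with a list median of -0.0094, a mean of 0.017 and a camera adjusted p of 0.66.

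Camera called 21 of the 31 lists, 17 up and 4 down, with the preset correlation and 1 with an estimated correlation, and fry called 17. Fry called all of these 21 but the neutrophil (fry adjusted p = 0.117), erythroid (0.051), interferon (0.117) and oxidative phosphorylation (0.13) lists. Its adjusted p was 6.2e-07 for classical monocytes, 3.7e-06 for B cells, 2.6e-05 for T cells and 0.0011 for the ribosome. Fry does not compare a list with the genes outside it. Without the 2 participants whose libraries did not match their own titles, 4014 genes changed, 1880 higher and 2134 lower, and camera called 21 lists.

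The letters in the sample titles allowed a comparison of the change between sets of participants. No gene passed edgeR's test of a difference between the 6 letters (0 of 13795 genes). Only 111 genes, 0.805%, had an unadjusted p under 0.05, fewer than the 5% that chance gives, so the test was conservative here and does not show that the changes were alike. The mean log2 change of APP ran from 0.085 to 0.67 over the letters. APP was higher in 5 of 5 participants of letter A, 3 of 4 of B and 3 of 5 of C. It was higher in 4 of 5 of D, 3 of 5 of E and 2 of 4 of F, with an SD of 0.70 in C and in F. The mean change of the classical monocyte markers lay between 0.19 and 0.36, that of the B cell markers between -0.39 and -0.20, and that of the glucocorticoid-responsive genes between 0.19 and 0.32. The letter means had the same sign in all 6 letters for APP and for these lists. Granule genes of immature neutrophils ran from -0.44 to 1.02, erythroid genes from -0.14 to 0.64 and neutrophil markers from -0.099 to 0.44.

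**Figure D4:**
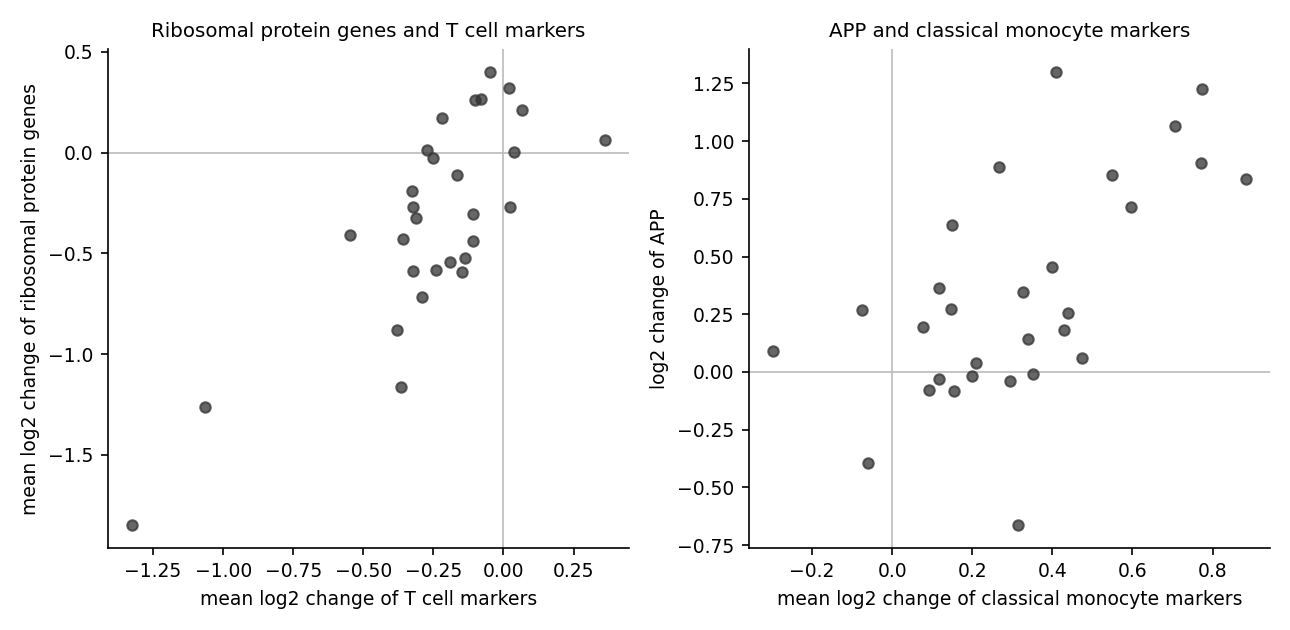
Change from baseline to day 10 in each of 29 participants (points), with the mean log2 change of T cell markers (x axis) against that of ribosomal protein genes (y axis) at the left, and that of classical monocyte markers (x axis) against the log2 change of APP (y axis) at the right. Pearson's r is 0.785 at the left (rho 0.676, permutation p of r 1e-05, the smallest the permutations can give; 0.553 without the 2 participants farthest from the median) and 0.608 at the right (rho 0.55, p = 0.00051; 0.616 without 2 participants).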

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

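The alternatives chosen only after the result was seen were the fit without the 2 participants whose libraries did not match, the offset for GC content and length, and the covariates for T and B cell, monocyte, platelet and immediate early scores and for alignments that were not unique. The count of 4477 changed genes (2322 higher, 2155 lower) stayed within 1.5 times under both other scalings, both other filters, DESeq2, both limma-voom fits, without globin genes, without the participant with the differing title, without the participants that did not match (4014), with the GC and length offset (5144; 2105 higher, 3039 lower) and without title letters A, B, E and F. Of the 5144 genes called with the GC and length offset, 3728 were among the 4477, all in the same direction. Leaving out each participant gave 3452 to 5156 genes, 1797 to 2629 higher and 1655 to 2585 lower. The split moved with upper quartile scaling (1510 higher, 3245 lower), and without title letter A 1538 genes were higher. Without letter C, 2320 genes changed (1158 higher, 1162 lower), and without letter D 2818 (1430 higher, 1388 lower), in fits with fewer participants. With no replicate block, that is without the paired design, 1379 genes changed (552 higher, 827 lower), as differences between people then count as error, 46 of 115 named genes missed the threshold, and APP kept its side of the threshold (log2 change 0.30, adjusted p = 0.0433). Camera then called 21 lists, without the oxidative phosphorylation list (adjusted p = 0.0644) and with the cell cycle list (adjusted p = 0.0187, but 0.686 with an estimated correlation, with a median of -0.0072 and 0 members past the threshold). A test against a fold of 1.2 left 64 genes (41 higher, 23 lower). The spread of the estimates also decides this count, as 201 of the 4477 genes had changed by over 1.5-fold.

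Covariates lowered the count: erythroid, neutrophil and T cell scores to 189 (134 higher, 55 lower), T and B cell scores to 97 (45 and 52), the monocyte score to 174 (88 and 86), the immediate early score to 322 (199 and 123), the platelet score to 1159 (633 and 526), the share of reads in no feature to 1011 (572 and 439) and that of alignments that were not unique to 1193 (662 and 531). Of these, 137, 52, 55, 319, 1123, 997 and 1149 had also changed without the covariate, all in the same direction. The cause was not tested. The lists called fell from 21 to 6 with the erythroid, neutrophil and T cell scores, to 12 with the T and B cell scores, to 9 with the monocyte score and to 1 with an estimated correlation, which weakens the test of a list whose genes move together. With the preset correlation some lists were called the other way, and none of these calls held with an estimated correlation. The interferon list had medians of -0.15, -0.15 and -0.18 under these 3 sets of scores (estimated correlation adjusted p = 0.698, 0.305 and 0.752), the neutrophil markers -0.17 under the T and B cell scores and -0.22 under the monocyte score (0.239 and 0.802), and the inflammatory list -0.068 under the T and B cell scores (0.365). The erythroid list had -0.089 with the share of reads in no feature as a covariate (0.713), with 0 members past the threshold. Lists called under these scores but not in the first fit were also lost with an estimated correlation: the plasma cell markers under the first 2 sets (0.698 and 0.699), the basophil markers (0.539 and 0.802) and the ubiquitin list (0.694 and 0.752) under the last 2, and the cytotoxic lymphocyte markers under the monocyte score (0.752). Under all 3 sets camera lost the lists of non-classical monocytes, T cells, immediate early genes, amyloid precursor protein, synapses, ribosome, oxidative phosphorylation, hypoxia, heat shock, oxidative stress and coagulation. A list's change is removed by construction where its own score is a covariate, as for the T cell list under the first 2 sets. The other settings called 17 to 23 lists. The letter comparison had 0 genes under all 3 of its settings, with 111, 53 and 115 genes at an unadjusted p under 0.05.

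APP kept its direction and its side of the threshold under both other scalings, both other filters, the other tools, the GC and length offset and without any participant or letter (leaving out each participant gave log2 changes from 0.30 to 0.37). It missed the threshold with the erythroid, neutrophil and T cell scores (0.059), the T and B cell scores (0.16), the platelet score (0.24), the immediate early score (0.21), the share of reads in no feature (0.31), alignments that were not unique (0.24) and in the test against a fold of 1.2 (0.33), and it was -0.00097 with the monocyte score. Adjusted p values ran from 0.00109 with DESeq2 to 0.997 with the monocyte score. The cause was not tested beyond the weighing of APP under the other observations.

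Of 115 other named genes, none changed sign under another scaling, filter (109 were tested with a minimum count of 50) or tool, or without the participant with the differing title, the participants that did not match or any title letter. Leaving out each participant was summarised for the counts and APP and not for these genes. With the erythroid, neutrophil and T cell scores the log2 change turned for RPL34 (0.18), COMMD6 (0.13), RPL39 (0.076), RPL9 (0.38), RPL26 (0.095), RPL31 (0.22), ZNF302 (0.22), GZMK (0.14), MX2 (-0.074), PARP14 (-0.14), STAT2 (-0.14), PSME3 (-0.00031), PSMD2 (-0.031), PSMF1 (-0.025), RNF123 (-0.0061), UBE2C (-0.13) and AEN (0.018). With the T and B cell scores it turned for RPL9 (0.060), FPR2 (-0.089), GZMK (0.056), MX2 (-0.085), PARP14 (-0.12), STAT2 (-0.096), UBE2C (-0.052) and AEN (0.00023). With the monocyte score it turned for CES1 (-0.0068), RPL9 (0.18), ZNF302 (0.14), HAL (-0.012), CXCR2 (-0.056), FPR2 (-0.076), TNFRSF17 (0.11), GZMK (0.15), SLC29A1 (-0.095), PTGDR2 (-0.020), MX2 (-0.22), PARP14 (-0.16), STAT2 (-0.17), LRP1 (-0.091), PSME3 (-0.011), PSMD2 (-0.045), RPS27A (0.0018), UQCRC1 (-0.016), TIMP2 (-0.00069), ICAM1 (-0.10), SESN2 (-0.018) and AEN (0.0083). None of these turned values passed the threshold, and the cause was not tested. Without a filter 3570 of 22291 genes changed.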

Other observations

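The relations between changes and the choice of genes in the first 2 paragraphs were chosen only after the results were seen, and the tests of explanations for the ribosomal protein genes, APP and the glucocorticoid-responsive genes were set before those tests were run. A set of 21 genes, 13 higher and 8 lower, passed the threshold in the same direction without cell scores and with each of the 3 sets of cell scores as covariates (erythroid, neutrophil and T cell; T and B cell; monocyte). The highest was DAAM2, a formin of Wnt signalling, with a log2 change of 1.60 (SE 0.17, higher in 29 of 29) from 2.11 ± 1.61 CPM at baseline (SD, n = 29), and 1.55, 1.87 and 1.503 with the covariates. Others were CYP1B1, a cytochrome of steroid and hydrocarbon metabolism (0.62, and 0.92, 0.83 and 0.65 with the covariates), VCAN (0.64, and 0.47, 0.41 and 0.25), the glucocorticoid-responsive genes TSC22D3 (0.45, and 0.40, 0.38 and 0.42) and DDIT4 (0.49, and 0.50, 0.48 and 0.58), DAPK1 (0.43, and 0.34, 0.38 and 0.29) and the steroid sulfatase gene STS (0.40, and 0.41, 0.38 and 0.43). On the lower side were CNTNAP2, a neurexin family gene (-0.89, and -0.78, -0.72 and -0.86), LINC00926 (-0.64, and -0.39, -0.26 and -0.43), SSTR3 (-0.43, and -0.49, -0.42 and -0.42) and HAPLN3 (-0.43, and -0.26, -0.32 and -0.34).

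Participants whose lymphocyte genes fell more also had larger changes of other groups. Over 29 participants and 10 relations, the change of the T cell markers went with that of the B cell markers (Pearson r = 0.777, Spearman rho = 0.681), of the ribosomal protein genes (0.785 and 0.676) and, with the opposite sign, of the classical monocyte markers (-0.729 and -0.656) and the glucocorticoid-responsive genes (-0.679 and -0.564), with adjusted permutation p of r at or below 0.00016. The smallest p the permutations can give is 1e-05. Without the 2 participants farthest from the median, r was 0.613, 0.553, -0.644 and -0.507, and within title letters 0.814, 0.804, -0.749 and -0.734. The ribosomal protein genes also moved with the nuclear genes of oxidative phosphorylation (r = 0.882, rho = 0.898, 0.878 without 2 participants). Their relation to the B cell markers (r = 0.611, rho = 0.434) rests in part on 2 participants, without whom r was 0.346 (p = 0.0767). APP moved with the classical monocyte markers (r = 0.608, adjusted p = 0.000729; rho = 0.55; 0.616 without 2 participants; 0.653 within letters). Its relations to the platelet genes (r = 0.399, rho = 0.431, adjusted p = 0.036) and the T cell markers (r = -0.425, rho = -0.449, adjusted p = 0.0256) were weaker and came to 0.371 (p = 0.0563) and -0.317 (p = 0.107) without 2 participants. The glucocorticoid-responsive genes were not shown to move with the monocyte markers (r = 0.339, rho = 0.193, adjusted p = 0.0726 and 0.315). Without the 2 participants whose libraries did not match, APP had r of 0.59 with the monocyte, 0.33 with the platelet and -0.36 with the T cell markers. Levels are relative to the same library totals, so a larger share of 1 group can lower others. The permutation p does not allow for this.

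Ribosomal protein genes fell by a median of 0.31 on the log2 scale, and genes that fell had a lower GC content (median 45.7%) than genes that rose (52.7%). Across 9521 genes the log2 change went with GC content (Spearman rho 0.334, and 0.337 without the ribosomal protein genes). Removing each library's trend on GC content and transcript length left the median at -0.292, which argues against the trend on these values as the whole cause. Length was that of the longest listed transcript, so a bias tied to shorter transcripts of these genes was not tested. With T and B cell scores as covariates the median was -0.0239, so fewer lymphocytes in the day 10 tubes may account for the fall, but the monocyte score (-0.0040) and the erythroid, neutrophil and T cell scores (0.0039) removed it as well, so lymphocytes are not singled out. The scores are RNA measures of the same libraries, and a common change inside lymphocytes would lower both. No cell counts were used here.

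APP rose by 0.33. After the GC and length offset it was 0.293 (95% interval 0.141 to 0.445), which argues against that bias. With the monocyte score as a covariate it was -0.000972 (-0.215 to 0.213), so more monocyte RNA per tube is a candidate explanation, but the erythroid, neutrophil and T cell scores took it to 0.059 as well, so monocytes are not singled out, and a rise of APP inside monocytes that also changed their markers would match too. With the platelet score it was 0.241 (0.0624 to 0.42), and a part from platelets cannot be told apart from none because the interval reaches below the bound of 0.10 set for that test. The blast exposure that the design names stays untested, as no unexposed library was used here.

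Glucocorticoid-responsive genes rose by a median of 0.22. The median was 0.197 after the GC and length offset and 0.182 with the immediate early score as a covariate. This argues against that trend and against what that score measures as the whole cause. Other library and handling differences were not weighed, and the camera call with an estimated correlation was lost with the offset (adjusted p = 0.0774). With the T and B cell scores the list's median was 0.138, with 3 members higher, and a part from lymphocytes was not tested. With the monocyte score, and without the 1 member shared with the monocyte lists, it was 0.126 against 0.217 before, between the bounds set for that test, so a part from monocytes cannot be told apart from none. A hormonal response to training or exposure is a hypothesis, and no hormone was measured here.

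The count of changed genes was higher with the real time points than in any random exchange of them. Exchanging baseline and day 10 at random within participants gave at most 1690 genes in 39 exchanges against 4477. Thus 1 of 40 arrangements, the real one, gave as many, which is the smallest share that 39 exchanges can give. This argues against chance assignment of the time points at that level and does not exclude it. Of the 39 exchanges 37 gave 0 genes. The other 2 gave 1690 and 71, so a random exchange can also give many calls.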
